A study of Mus musculus with 12 samples.

How the data were processed

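RNA was measured in 12 samples of immature dendritic cells grown from C57BL/6 mouse bone marrow with GM-CSF. Per the labels' protocols, cells sat in wells of a plate with medium alone, LPS at 500 ng/ml, or Msg purified with SDS or with lyticase, each at 5 µg/ml, for 24 h, with 3 wells per treatment, and RNA was extracted well by well. LPS is a component of the outer membrane of Gram-negative bacteria that is sensed by Toll-like receptor 4. Msg is the major surface glycoprotein of the lung fungus Pneumocystis, here of Pneumocystis murina. SDS is a detergent, and lyticase is an enzyme preparation that digests fungal cell wall glucans. The labels speak of wells in triplicate and name no separate animals or cultures. The p-values below therefore measure the spread between these samples, which may be technical.

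The deposited table holds 1 log2 value per probe set and array. Per the submitters' processing notes the tools were Partek and RMA (robust multi-array average), for which no version is given. RMA subtracts background by a model, quantile normalizes the arrays and summarises the probes of a set. No build of the genome is named, so no coordinates are printed. The arrays were labelled with an Affymetrix whole transcript kit, per the labels. The table holds 35556 probe sets. A platform annotation of unknown date pairs 21789 of them with 1 gene symbol and 1621 with several, and does not list 12146. For 21698 probe sets the Entrez gene ID matched the RefSeq gene table, and 0 symbols were changed by the match. Where a symbol had more than 1 probe set, as for 999 symbols, the probe set with the highest mean over the 12 arrays was used. This left 19938 genes. Quantile normalization assumes that the arrays have about the same distribution of values, so a change of most genes in 1 direction would be removed. Scanner files were not used here, so no detection calls or scan dates entered the analysis. The highest values lie near 14.2, and saturation was not tested.

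All 12 arrays were fitted in 1 linear model with limma 3.58.1 (lmFit and eBayes, defaults) in R 4.3.3, with 4 group means and no further normalization or filter. The model has 8 residual and 3.42 prior degrees of freedom. Genes were called at a two-sided Benjamini-Hochberg adjusted p under 0.05 over the 19938 genes. Contrasts were each treatment minus media, lyticase-Msg minus SDS-Msg, LPS minus each Msg preparation, and a moderated F test over the 3 treatments. Intervals are 95% intervals from limma. Values are given as mean log2 signal ± SD with n = 3 arrays, and folds are 2 to the power of the log2 difference. With 3 arrays against 3, an exact permutation test of a single value cannot go below p = 0.1.

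Gene lists were tested with camera (limma) at its preset correlation of 0.01 between genes, Benjamini-Hochberg adjusted within each contrast. Camera compares a list's genes with all other genes. Each test was repeated with the correlation estimated from the data, and with fry, whose p tests whether a list's genes move on balance in 1 direction without comparing them with other genes. The 27 lists, 19 of function and 8 of cell type, cover co-stimulation and maturation, MHC class II and class I presentation, inflammatory and T cell polarizing cytokines, chemokines, the NF-kB pathway and its feedback, the type I interferon response, guanylate-binding and immunity-related GTPases, C-type lectins and fungal recognition, Toll-like and NOD-like receptors, inflammasome and pyroptosis, nitric oxide, itaconate and arginine, glycolysis, the TCA cycle and oxidative phosphorylation, cholesterol synthesis, the cell cycle, lysosome and phagocytosis, the unfolded protein response and amino acid stress, NRF2 and oxidative stress, and markers of conventional dendritic cells, macrophages, neutrophils, mast cells with basophils and eosinophils, lymphocytes, plasmacytoid dendritic cells, erythroid cells and stromal cells. Of the 434 genes in the lists, 8 are in more than 1 list.

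The contrasts, the lists, the alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to come after. The rule names, per contrast, the 8 called genes with the largest rise and the 8 with the largest fall whose arrays do not overlap between the groups, leaving out predicted genes, then the called member of each list with the largest rise and fall, and a panel of 20 genes whether called or not. Predicted genes are counted but not named.

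The fit was tested on simulated data with the 12 arrays' design, in which 200 of 19938 genes were changed in 20 draws. It recovered 25.5% of genes changed by 0.3 log2, 67.4% at 0.5, 97.5% at 1 and 100% at 2, with 4.79% of its calls false and 0 calls in an unchanged comparison. A list of 21 genes moved by 0.1 log2 was recovered in 100% of the draws. The simulated genes vary independently of each other, so this list result is a best case. The gene recovery holds for 200 changed genes and no differences between arrays. With fewer changed genes the adjusted threshold is stricter, so recovery in the Msg contrasts may be lower.

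The alternatives were median centring of each array, a further quantile normalization, 2 filters on dim genes, a floor under low values, a trend and robust variance model, array weights, the replicate number as a block, all probe sets, stricter thresholds, fitting only the groups compared, and leaving out each array of the groups compared in turn. Cyclic loess, comparisons with no array in common and leaving out a pair of arrays were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.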

Results

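The series asks whether the major surface glycoprotein (Msg) of Pneumocystis murina activates dendritic cells. Genome-wide expression was measured on 12 arrays, 3 each from immature dendritic cells kept in medium, with LPS, with SDS-Msg or with lyticase-Msg for 24 h. The number of arrays sets the precision: the median standard error of a log2 difference between groups was 0.086 and the median 95% interval reached 0.19 to either side. Array medians lay between 7.25 and 7.33 on the log2 scale. Within-group correlations across genes ran from 0.992 to 0.995. LPS arrays correlated with media arrays at 0.972 to 0.976, lyticase-Msg arrays at 0.989 to 0.996 and SDS-Msg arrays at 0.993 to 0.996. The component that carried 75% of the variance placed the LPS arrays at 53.8 to 55.0 and the other 9 arrays at -19.0 to -17.1. The next carried 4.91%, with media replicate 3 at 15.3, lyticase-Msg replicate 2 at -12.5 and LPS replicate 3 at -13.0.

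LPS was the control known to mature dendritic cells. Among the genes named by the rule, genes of the type I interferon response had the largest rises, from Ifit3 down to Ifi205. Ifit3, an interferon-induced antiviral gene, went from 5.86 ± 0.18 in media to 12.60 ± 0.0059 with LPS, a 106-fold rise (95% interval 90.3 to 125). Ifit2 rose 92.2-fold, Rsad2 84.1-fold, Ifit1 76.3-fold, Ifi205 74.2-fold and Cmpk2 42.9-fold. Il12b (59.9-fold) and Cxcl10 (52.1-fold), of the cytokine and chemokine lists, rose more than Cmpk2. All 29 tested genes of the interferon list rose, over all genes and adjusted over the list alone, with a median log2 difference of 3.79 (camera, adjusted p = 1.25e-37, and adjusted p = 0.00425 with an estimated correlation). The guanylate-binding and immunity-related GTPases act against intracellular pathogens, and 9 of the 18 listed were among the genes tested. Probe sets with several symbols were left out of the tests, so the array may hold more of the family. All 9 rose by either count, with a median of 3.39 and Gbp4 28.1-fold up (camera, adjusted p = 4.25e-13, and 0.00425 as the adjusted p with an estimated correlation).

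Cytokine genes rose in 20 of 22 cases, with a median rise of 2.83-fold (camera, adjusted p = 3.19e-17, adjusted p = 0.00479 with an estimated correlation). Adjusted over the list alone, 20 rose and 1 fell. Il12b, a cytokine subunit that drives T helper responses, rose 59.9-fold (95% interval 53.5 to 67.0), from 7.07 ± 0.058 to 12.97 ± 0.029. Il10, an anti-inflammatory cytokine, rose 23.8-fold from a low level in media (4.64), and its log2 difference of 4.57 became 3.25 with a floor under low values. The rise was 14.3-fold for Il6, 11.5-fold for Il23a, 2.82-fold for Tnf and 1.86-fold for Il1b. Of 21 chemokine genes 17 rose and 1 fell, with a median of 1.01 (camera, adjusted p = 1.09e-10, and adjusted p = 0.00453 with an estimated correlation). Among chemokines adjusted over the list alone, 17 rose and 2 fell. Cxcl10, which attracts activated T cells, rose 52.1-fold and Ccl22 2.50-fold, while Ccl6 fell by 0.29 log2. Ccl17 rose 1.12-fold from a level of 13.74, near the top of the scale (adjusted p = 0.0273). That call is lost in 5 of 12 alternatives, with adjusted p between 0.00346 and 0.0997. Genes of the NF-kB pathway and its feedback inhibitors rose in 21 of 21 cases by either count, with a median of 0.96 (camera, adjusted p = 8.31e-18, adjusted p = 0.00425 with an estimated correlation). Ptgs2, the inducible cyclooxygenase, rose 7.55-fold.

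Maturation genes rose in 19 of 20 cases by either count, with a median of 1.04 (camera, adjusted p = 2.44e-16, and adjusted p = 0.0126 with an estimated correlation). The co-stimulatory receptor Cd40 rose 13.3-fold (95% interval 11.9 to 14.7), Cd86 2.49-fold, Cd80 1.79-fold, the maturation marker Cd83 1.87-fold and Ccr7, the receptor that guides dendritic cells to lymph nodes, 1.90-fold. MHC class I presentation genes rose in 12 of 13 cases by either count, with a median of 0.96 and the peptide transporter Tap1 4.06-fold up (camera, adjusted p = 2.53e-11, adjusted p = 0.00425 with an estimated correlation). MHC class II presentation genes were not called as a list by camera (median 0.0062, mean -0.090, test direction down, adjusted p = 0.601), but were by fry (adjusted p = 0.000505). Of 12 tested genes 1 rose and 3 fell by either count, the class II transactivator Ciita rising by 0.34 and the peptide-loading chaperone H2-DMa falling by 0.69. H2-Ab1, a class II chain, lay at 13.24 ± 0.010 with LPS and 13.22 ± 0.019 in media (difference 0.028, 95% interval -0.072 to 0.13, adjusted p = 0.688), and saturation at this brightness was not tested.

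Several sensor and effector lists were called by camera at the preset correlation and by fry, but not by camera with an estimated correlation. For nitric oxide, itaconate and arginine genes 6 of 9 rose and 1 fell, with the inducible nitric oxide synthase Nos2 12.3-fold up and the arginase Arg1 lower by 1.32-fold (median 1.10, camera, adjusted p = 0.00178, and adjusted p = 0.126 with an estimated correlation). Adjusted over the list alone, 6 rose and 2 fell. Inflammasome genes rose in 9 of 14 cases and fell in 3 by either count, with Casp4, a caspase that binds LPS inside the cell, 4.95-fold up and Nlrp1b down by 1.99-fold (median 0.62, camera, adjusted p = 0.00317, adjusted p = 0.159 with an estimated correlation). Of 21 Toll-like and NOD-like receptor genes 13 rose and 5 fell, and 14 and 5 adjusted over the list alone (median 0.39, camera, adjusted p = 0.00190, and adjusted p = 0.139 with an estimated correlation). Tlr3, a receptor for double-stranded RNA, rose 5.15-fold, Tlr2 rose by 0.30, and Tlr4, the receptor for LPS itself, fell by 0.60.

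Cell cycle genes fell with LPS in 25 of 26 cases by either count, with a median log2 difference of -0.62 (camera, adjusted p = 2.53e-11, and adjusted p = 0.00479 with an estimated correlation). Kif20a, a kinesin of cell division, was 2.09-fold lower, and Tyms, a thymidylate synthesis enzyme, rose 1.48-fold. Cholesterol synthesis genes fell in 14 of 16 cases and rose in 1 by either count, with a median of -0.71, Dhcr7, the last enzyme of the pathway, 2.94-fold lower and Idi1 1.36-fold higher (camera, adjusted p = 3.72e-07, adjusted p = 0.0644 with an estimated correlation). TCA cycle and oxidative phosphorylation genes fell in 15 of 21 cases, and in 17 adjusted over the list alone, with a median of -0.22 and the fumarase Fh1 1.75-fold lower (camera, adjusted p = 9.40e-05, and adjusted p = 0.131 with an estimated correlation). Of 23 genes of C-type lectins and fungal recognition 13 fell and 5 rose, and 14 and 5 adjusted over the list alone, with a median of -0.29 (camera, adjusted p = 0.0281, adjusted p = 0.344 with an estimated correlation). This call was also lost with genes above the 25th percentile of level (0.0660) and above the median (0.230), and over 18 alternatives the adjusted p ran from 6.28e-06 to 0.344. Cd209a fell by 1.88, the mannose receptor Mrc1 by 0.68 and Clec7a, the receptor for fungal beta-glucan, by 0.51, while the soluble pattern receptor Ptx3 rose by 1.30. The largest falls of single genes were in Pvt1, a long non-coding RNA (6.08-fold), Gcsh of the glycine cleavage system (5.79-fold), Scel (5.76-fold), the inhibitory receptor Cd200r1 (5.05-fold), Pald1 (4.84-fold), Otulinl (4.71-fold), Lpin1 of lipid synthesis (4.65-fold) and Sh2d1b1 (4.57-fold). A dimmer probe set of Pvt1, at a level of 3.32, differed by 0.069 (adjusted p = 0.469).

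Single markers of other cell types moved with LPS beside these groups, while camera in the main fit did not call 7 of the 8 cell type lists. Fry called 5 of these 7: neutrophil (adjusted p = 0.00336), mast cell, basophil and eosinophil (9.82e-06), lymphocyte (0.0469), plasmacytoid (1.51e-05) and erythroid (0.00472). Cxcr2, a neutrophil chemokine receptor, fell by 1.96 and Csf3r rose by 0.39 (5 of 15 neutrophil genes fell and 2 rose, median -0.035, camera, adjusted p = 0.568). C1qa fell by 1.28 and the transcription factor Maf rose by 3.79 among macrophage genes (7 of 13 fell and 3 rose, adjusted p = 0.422). There the median was -0.35, the mean 0.060 and the test direction down. Btla rose by 1.92 and Kmo fell by 1.67 in the conventional dendritic cell list (4 of 14 rose and 5 fell, median 0.048, adjusted p = 0.649). In the plasmacytoid list Tcf4 rose by 1.54 and Spib fell by 1.05 (2 of 8 rose and 2 fell, median 0.11, adjusted p = 0.453). Hdc, the histamine-forming enzyme, rose by 2.51 in the mast cell, basophil and eosinophil list, of which 4 of 14 rose and 1, Ccr3, fell by 0.20 (median 0.086, adjusted p = 0.112). With adjustment over the list alone, 3 of these rose and 1 fell. Camera called the mast cell list after cyclic loess (adjusted p = 0.0448) and without LPS replicate 3 (0.04095). Ccr3 lost its call in 7 of 12 alternatives, with adjusted p between 0.0171 and 0.149. Il7r rose by 0.87 and Klrb1c fell by 0.88 in the lymphocyte list (2 of 13 rose and 1 fell, median 0.034, adjusted p = 0.546), Klrb1c at levels so low that a floor at the 25th percentile removes the difference. Car2 rose by 0.42 in the erythroid list (2 of 7 rose, median 0.21, adjusted p = 0.158). The stromal list was called up, with 3 of 12 genes rising and Kdr, a receptor of endothelial cells, 7.16-fold up (median 0.12, camera, adjusted p = 0.0250, and adjusted p = 0.271 with an estimated correlation). It was also lost with genes above the 25th percentile of level (0.0573), above the median (0.0809) and with a floor under low values (0.0505), and over 18 alternatives the adjusted p ran from 0.000103 to 0.271. For each of these lists except the mast cell one the counts were the same adjusted over the list alone.

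Over all genes, LPS raised 2919 and lowered 4672 of 19938 (limma, 7591 in all, of which 61.6% fell). At a change of at least 2-fold, 563 rose and 423 fell, so that fewer fell than rose. The excess of falls also depends on normalization, the share being 52.5% after cyclic loess.

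**Figure D1:**
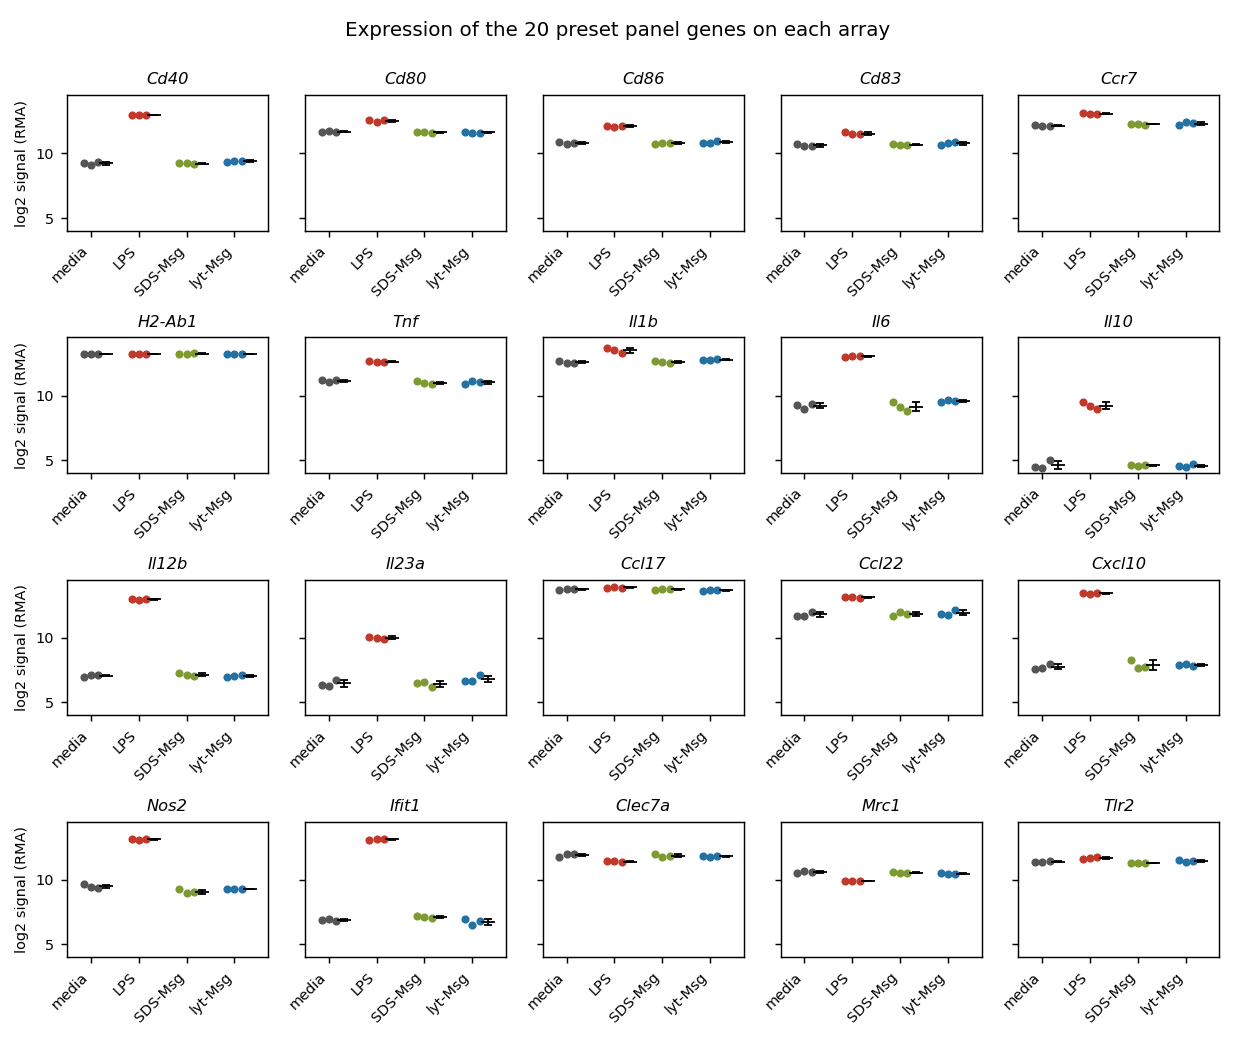
Log2 signal of the 20 panel genes on each array (vertical axis) for the 4 groups (horizontal axis). Points are the 3 arrays of a group, and the black mark and bar beside them are their mean and SD. The LPS points stand apart for Il12b (12.97 against 7.07 in media) and Cd40 (12.98 against 9.25), while the points of both Msg preparations lie close to media.

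Lyticase-Msg was compared with media to ask whether Msg freed by enzyme digestion acts on dendritic cells. None of the 20 panel genes passed the test, and their log2 differences ran from -0.23 to 0.38. Il6 lay at 9.58 ± 0.11 against 9.20 ± 0.19 in media (difference 0.38, 95% interval 0.072 to 0.69, adjusted p = 0.615) and Il23a at 6.79 against 6.47 (0.33, -0.011 to 0.66, adjusted p = 0.646). Nos2 lay at 9.28 against 9.51 (-0.23, -0.41 to -0.052, adjusted p = 0.608). Cd40 differed by 0.15 (-0.00083 to 0.30), Cd86 by 0.076 (-0.060 to 0.21), Cd80 by -0.066 (-0.20 to 0.070), Il12b by -0.023 (-0.18 to 0.14), Cxcl10 by 0.14 (-0.18 to 0.46) and Ifit1 by -0.11 (-0.34 to 0.11). The intervals of the 20 genes stayed between -0.42 and 0.69, and 16 of them included 0.

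Camera called 4 of 27 lists in lyticase-Msg against media, by shifts of under 0.1 log2, and 0 were called with an estimated correlation or by fry. Cholesterol synthesis genes had a median of -0.086, with 14 of 16 below media (adjusted p = 0.000213), and NF-kB genes a median of 0.086, with 17 of 21 above media (adjusted p = 0.00341). Lysosome and phagocytosis genes had a median of -0.038 (18 of 22 below, adjusted p = 0.0115) and Toll-like and NOD-like receptors one of -0.053 (14 of 21 below, adjusted p = 0.0180). For each of the 4 lists the adjusted p was 0.448 with an estimated correlation. Over all genes 0 members were called. Adjusted over the list alone, Hmgcs1 and Lss fell in the cholesterol list, Ptgs2 rose in the NF-kB list and Tlr1 fell in the receptor list, all named after their values were seen. Without media replicate 2 the NF-kB call was lost (adjusted p = 0.0755), and the receptor call was lost without media replicate 1 (0.0741) or lyticase-Msg replicate 2 (0.0662). Over 18 alternatives the adjusted p ran from 1.38e-05 to 0.448 for cholesterol synthesis, 1.63e-05 to 0.448 for NF-kB, 0.00103 to 0.448 for lysosome and phagocytosis and 0.0105 to 0.448 for the receptors. The lysosome and receptor calls were also lost with genes above the median level (0.0809 and 0.135), after cyclic loess (0.105 for both) and without media replicate 3 and lyticase-Msg replicate 2 together (0.235 and 0.0740). Co-stimulation and maturation genes, at a median of 0.074, missed the threshold (adjusted p = 0.0561) but were called in 11 of the 18 alternatives (0.00313 to 0.522). Glycolysis genes, at -0.041, missed it by as much. They were called lower with median centring (0.0273), the floor (0.00634), the trend and robust model (0.0169) and without lyticase-Msg replicate 2 (0.0480). Cytokines, at 0.045 (adjusted p = 0.1305), were called higher in 4 of 18 (0.0109 to 0.539). The type I interferon list had a median of 0.047 (adjusted p = 0.376). It was called in 2 of 18 alternatives, without lyticase-Msg replicate 2 (0.0480) and without that array and media replicate 3 (0.0312), the adjusted p running up to 0.969 and the median from 0.0094 to 0.086.

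In the limma fit 0 genes differed between lyticase-Msg and media, with 1550 at an unadjusted p under 0.05 where 997 would be so by chance on average. The spread of this count by chance was not estimated, and genes that vary together can widen it. The smallest adjusted p was 0.261. Without media replicate 3 a single gene was called, Rxfp3 (0.67, adjusted p = 0.0289), chosen after its values were seen.

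SDS-Msg was compared with media to ask the same of Msg extracted with detergent. Again 0 of the 20 panel genes passed the test, with log2 differences from -0.42 to 0.24. Nos2 lay at 9.09 against 9.51 in media (difference -0.42, 95% interval -0.60 to -0.24, adjusted p = 0.638) and Ifit1 at 7.12 against 6.88 (0.24, 0.013 to 0.47, adjusted p = 0.942). Cd40 differed by -0.025 (-0.18 to 0.12), Cd86 by 0.0040 (-0.13 to 0.14), Cd80 by -0.066 (-0.20 to 0.070), Tnf by -0.15 (-0.31 to 0.0085), Il6 by -0.062 (-0.37 to 0.25) and Il12b by 0.067 (-0.095 to 0.23). The intervals stayed between -0.60 and 0.47, and 18 of 20 included 0.

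Camera called 0 of 27 lists in SDS-Msg against media, as did camera with an estimated correlation and fry. The cholesterol synthesis list had the smallest adjusted p, 0.0989, with a median of -0.065. It was called lower in 3 of 18 alternatives, with a floor under low values (0.0149), with a trend and robust variance model (0.0375) and without media replicate 2 (0.0271), the adjusted p running up to 0.814. Co-stimulation and maturation genes had a median of 0.054 (adjusted p = 0.375) and the type I interferon list 0.034 (adjusted p = 0.314). The interferon list was called with genes above the median level (0.0220, the range over 18 alternatives reaching 0.851), and its median changed sign without SDS-Msg replicate 1 (-0.016). Adjusted over the list alone, Hmgcs1 fell and Fdps rose in the cholesterol synthesis list and Nos2 fell in the nitric oxide list, the cholesterol genes named after their values were seen. In the limma fit 0 genes differed, with 966 at an unadjusted p under 0.05 against 997 by chance and a smallest adjusted p of 0.248. Without media replicate 3 Rxfp3 alone was called here too (0.67, adjusted p = 0.0295).

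**Figure D2:**
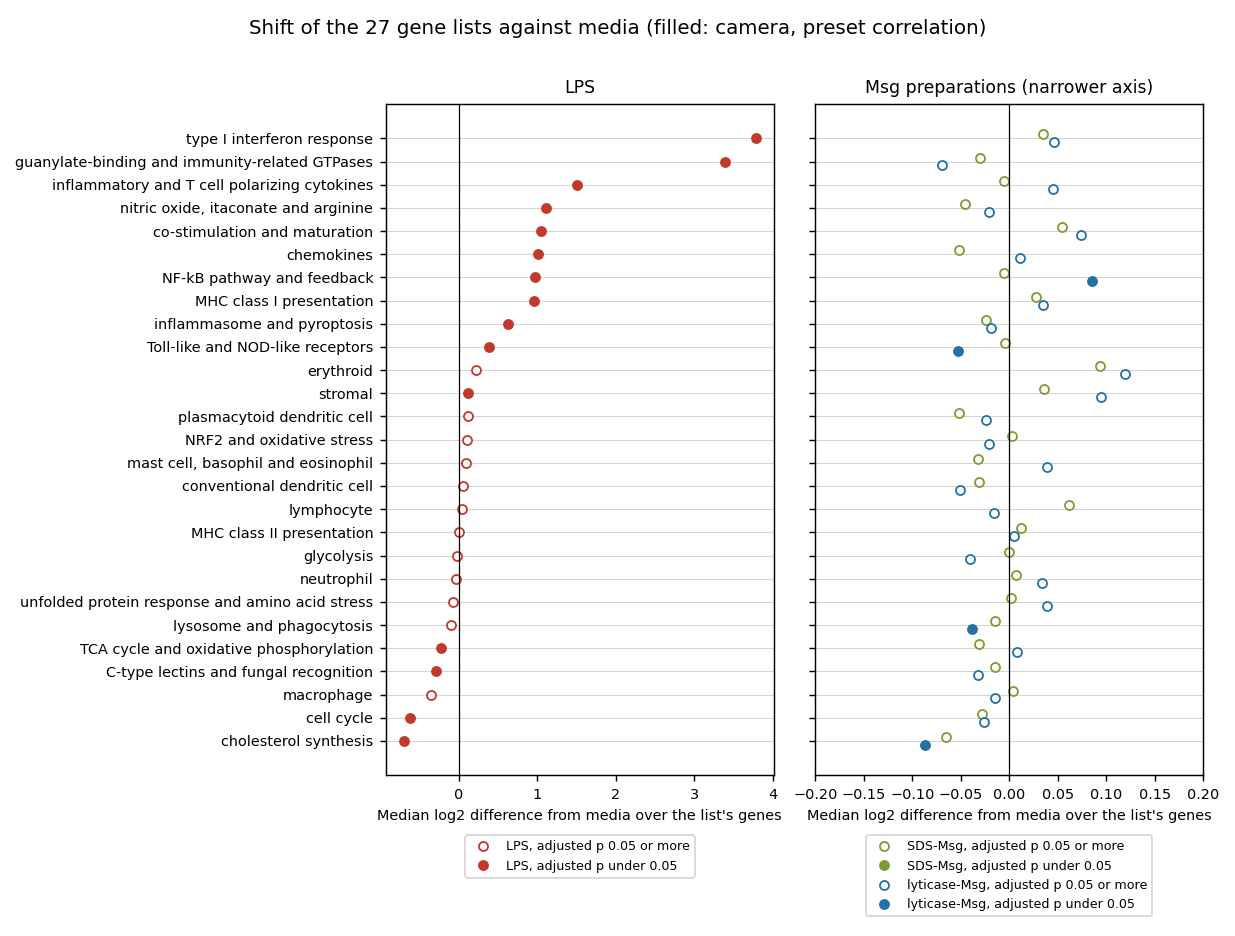
Median log2 difference from media (horizontal axis) of each of 27 gene lists (vertical axis), for LPS on the left and both Msg preparations on a narrower axis on the right. Filled points have a camera adjusted p under 0.05 at the preset correlation. LPS medians reach 3.79 for the interferon list, and the Msg medians with filled points lie between -0.086 and 0.086.

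The genes that answered LPS were then read in the Msg arrays. For 979 of the 986 genes changed at least 2-fold by LPS (99.3%), the 95% interval of the response lay within a 2-fold change for lyticase-Msg, and for SDS-Msg the count was the same. The median absolute log2 difference of these genes was 1.36 with LPS, 0.076 with lyticase-Msg and 0.060 with SDS-Msg. As a share of each gene's LPS response the median was 2.51% for lyticase-Msg (5th to 95th percentile -9.12% to 17.1%) and 0.641% for SDS-Msg (-10.2% to 12.7%). The media arrays enter both responses and the choice of genes, so unchanged groups need not give 0 here. With no array in common, slopes over genes with a 2-fold LPS difference were 1.28% (SE 0.65) for lyticase-Msg and -0.088% (SE 0.67) for SDS-Msg. Tested directly, 983 of the 986 genes differed between LPS and lyticase-Msg and 982 between LPS and SDS-Msg (limma). The LPS arrays in these tests also chose the 986 genes, so such counts largely follow from the choice. Over all genes 2681 were higher and 4573 lower with LPS than with lyticase-Msg, and 2799 higher and 4567 lower than with SDS-Msg. The moderated F test over the 3 treatments called 7105 genes.

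**Figure D3:**
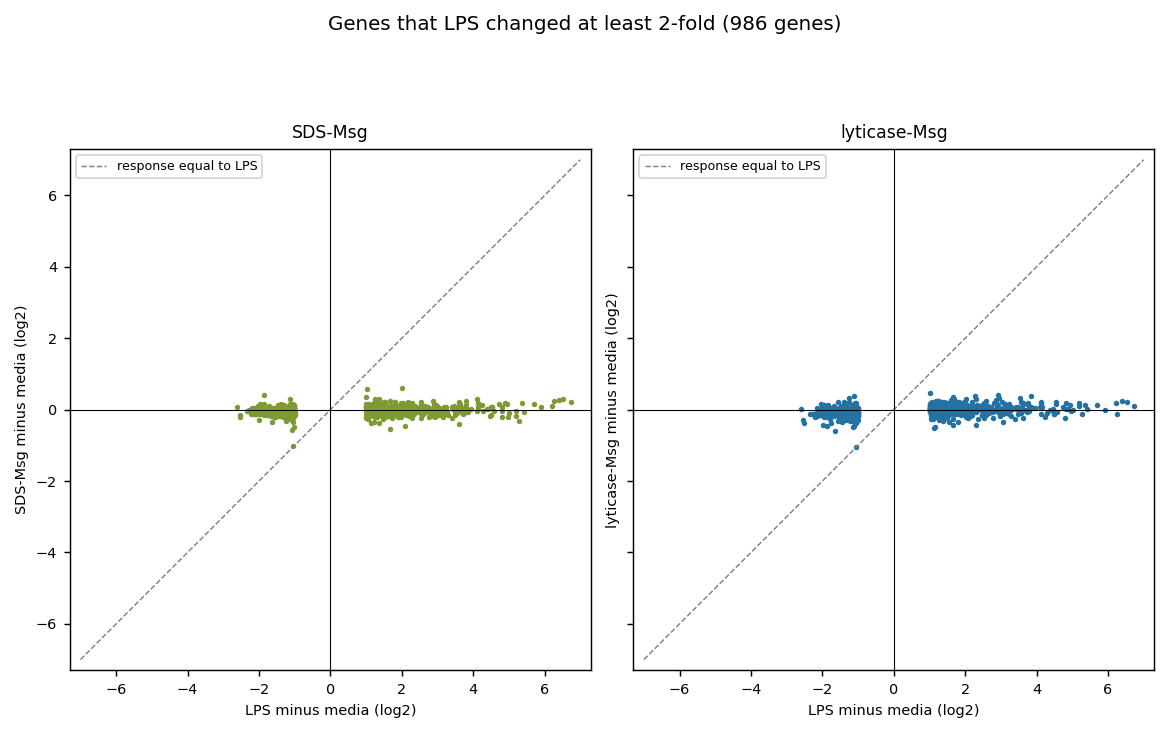
Log2 difference from media with SDS-Msg (left) and lyticase-Msg (right) on the vertical axis against that with LPS on the horizontal axis, 1 point per gene, for the 986 genes that LPS changed at least 2-fold. The dashed line marks a response equal to LPS. The points lie along the horizontal line at 0, with median absolute differences of 0.060 for SDS-Msg and 0.076 for lyticase-Msg. A single point lies on the dashed line, Mterf2, chosen after its values were seen.

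Lyticase-Msg and SDS-Msg were set against each other to ask whether the purification matters. Of the panel, Il6 was 0.45 higher with lyticase-Msg (95% interval 0.13 to 0.76, adjusted p = 0.992), Il23a 0.35 higher (0.017 to 0.69), Cd40 0.17 higher (0.024 to 0.32), Tlr2 0.17 higher (0.054 to 0.29), Il1b 0.20 higher (0.0055 to 0.39), Nos2 0.18 higher (0.0034 to 0.36) and Ifit1 0.36 lower (difference -0.36, -0.58 to -0.13, adjusted p = 0.954), none past the threshold. The intervals of the other 13 of 20 genes included 0. The NF-kB list was higher with lyticase-Msg by a median of 0.086, in 18 of 21 genes (camera, adjusted p = 5.16e-05, and adjusted p = 0.465 with an estimated correlation). Cytokines (median 0.052) and chemokines (0.043) were called higher and glycolysis genes (-0.044) lower, each with an adjusted p of 0.0478. With an estimated correlation the adjusted p was 0.690 for cytokines and 0.532 for both chemokines and glycolysis, and fry called 0 lists. Over all genes 0 members were called. Adjusted over the list alone, Osm and Inhba were higher among cytokines and Ptgs2 in the NF-kB list, named after their values were seen, with 0 among chemokines or glycolysis genes. Of the 4 lists, the NF-kB call held without each of the 6 lyticase-Msg and SDS-Msg arrays in turn. The other 3 calls were lost without lyticase-Msg replicate 3 (adjusted p 0.196 for cytokines, 0.341 for chemokines and 0.0662 for glycolysis), without SDS-Msg replicate 2 (0.123, 0.142 and 0.142) and without SDS-Msg replicate 3 (0.321, 0.130 and 0.130). Cytokines (0.0790) and glycolysis (0.0790) were lost without lyticase-Msg replicate 2 too, and glycolysis without replicate 1 (0.0925). Over 18 alternatives the adjusted p ran from 4.20e-07 to 0.465 for NF-kB, 0.00219 to 0.690 for cytokines, 0.00219 to 0.532 for chemokines and 0.00366 to 0.532 for glycolysis.

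The limma fit called 0 genes between the preparations, with 890 at an unadjusted p under 0.05 against 997 by chance. The smallest adjusted p was 0.372, for Ptgs2, 0.61 higher with lyticase-Msg and chosen after its values were seen. With a trend and robust variance model Ptgs2 was called (adjusted p = 0.0207). It was called too without SDS-Msg replicate 1 (0.0355), as was Nova1, chosen likewise, without lyticase-Msg replicate 3 (difference -0.96, adjusted p = 0.0396).

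The responses share the media arrays, so their correlation across genes lies above 0 by chance, and genes are not independent replicates. The log2 differences of LPS and lyticase-Msg correlated at r = 0.208, where unchanged groups with shared controls gave 0.50 in 100 simulations. LPS was left unchanged in the simulations too, so for pairs with LPS the simulated r is too high a mark. Real LPS differences vary far more, which lowers r even where the covariance exceeds the simulated one. The covariance was 0.0135 against a simulated 0.00554. For LPS and SDS-Msg r was 0.151 against 0.499, with a covariance of 0.00911 against 0.00553, and for lyticase-Msg and SDS-Msg r was 0.586 against 0.50, with 0.00840 against 0.00555. The 3 media arrays cannot be split into parts of 2, so part of any excess may come from the shared controls.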

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

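Cyclic loess, the interferon prediction, the separation of the arrays for a list and the bins by level were chosen after the results were seen, as were the patterns they address. The splits, the list tests, the estimated correlation and median centring were planned. Between lyticase-Msg and SDS-Msg the test of the difference itself called 4 gene lists: NF-kB genes (median log2 difference 0.08557) and, each at an adjusted p of 0.0478, inflammatory cytokines (0.05217), chemokines (0.04317) and glycolysis (-0.04362). With an estimated correlation the adjusted p was 0.465, 0.690, 0.532 and 0.532 in that order, and fry called 0 lists. Signal was also seen in probe sets that the comparisons leave out. Of the 12146 probe sets the annotation does not list, 1857 were called between LPS and media (867 up, 990 down), and of the 1621 with several symbols 383 were called (188 up, 195 down), against 0 of either kind in the other 3 contrasts tested.

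The higher NF-kB list with lyticase-Msg was found against both media and SDS-Msg. Both contrasts use the same 3 lyticase-Msg arrays, so they do not replicate each other. A difference between arrays that depends on the level of the gene is argued against as the source of the call at the preset correlation. After cyclic loess the larger of the camera adjusted p-values at that correlation was 7.10e-05. The estimated correlation and fry, which did not call the list in the main fit, were not run after cyclic loess. The result therefore does not show that the list moved. A weak response with the same make-up as the LPS response was not decided. The NF-kB mean moved by 8.74% of its LPS change, which predicts 0.36 for the type I interferon list. That list differed by -0.0046, a gap of -0.36 (SE 0.072). But the NF-kB list was picked after the results were seen because it moved, so its share may be too large. Over 988 genes with a 2-fold LPS difference the slope was only 1.38% (SE 0.64). Genes of the list varying together between wells stay open, with an adjusted p of 0.465 once the correlation is estimated, and over all alternatives the adjusted p ran from 4.20e-07 to 0.465. All 3 lyticase-Msg arrays lie above the 6 media and SDS-Msg arrays for this list (exact p = 0.0238), but of 27 lists chance gives 0.643 such cases in 1 or the other direction, and 1 list lies above and 1, glycolysis, below.

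More genes fell than rose with LPS. Arrays of 1 group with a shifted median are argued against as the cause, since centring each array raised the share of falls to 65.0%. A difference between arrays that depends on level cannot be told apart from a real excess of falls: cyclic loess lowered the share to 52.5% (52.2% to 52.8% with each array left out), and a correction for level also removes a true change that goes with level. With genes put in 4 equal bins by level, the median LPS difference from the dimmest bin up was 0.068, 0.050, -0.135 and -0.100. For lyticase-Msg minus media, with 0 called genes, these medians were 0.052, 0.052, -0.012 and -0.013. For SDS-Msg minus media, also with 0, they were 0.038, 0.040, -0.019 and -0.015. All of these contrasts share the media arrays, so part of the LPS pattern, mainly in the dim bins, may come from a difference of those arrays by level. A biological excess of falls stays open, as untested.

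Other splits of the arrays were run for each count. The overall F test called as many genes in 3 of 100 drawn splits of the 12 arrays into 4 groups, the real one included. That share speaks against no difference between any groups at all, and says nothing on the Msg groups. The real count was 7105 and the highest other 7167. The other 2 such splits keep the 3 LPS arrays together, as do all 6 drawn splits with at least 6750 calls, and the 93 that part them called at most 1 gene, so the count rests on LPS. For each contrast the 6 arrays allow 10 splits, too few for a share under 0.05. Gene counts were 7591 for LPS against media with 1 as the highest other, 0 with 1 for lyticase-Msg, 0 with 1 for SDS-Msg, 0 with 1 between the preparations, 7254 with 1 for LPS against lyticase-Msg and 7366 with 0 for LPS against SDS-Msg. Numbers of called lists were 15 with 12 as the highest other for LPS, 4 with 4 for lyticase-Msg, 0 with 3 for SDS-Msg and 4 with 5 between the preparations. Other splits of an LPS contrast still put the LPS arrays unevenly on the 2 sides. Part of the LPS effect therefore stays in the difference, and the rest widens the spread. So the 12 lists and the 0 or 1 genes of those splits are not chance levels.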

How the results depend on the processing

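Cyclic loess, the correlations with no array in common and leaving out media replicate 3 with lyticase-Msg replicate 2 were chosen after the data had been seen. LPS against media kept a count between 5900 and 9884 under every alternative except the 2-fold threshold, and of its called genes 6436 were shared with cyclic loess. Requiring a 2-fold change left 986 genes for LPS against media, 925 against lyticase-Msg, 973 against SDS-Msg and 983 in the F test, by construction. Lyticase-Msg and SDS-Msg against media stayed at 0 genes under every alternative except without media replicate 3, and their leave-one-out counts ran from 0 to 1. Between the preparations the count was 1 with a trend and robust variance model and 0 to 1 with single arrays left out. With single arrays left out, counts ran from 6693 to 7279 for LPS against media, 6600 to 6921 against lyticase-Msg, 6692 to 6980 against SDS-Msg and 6180 to 7059 in the F test. Numbers of called lists moved more, and the cause was not tested unless named. For LPS they were 8 with an estimated correlation and 24 with fry, which asks another question, and 15 to 16 with single arrays left out. For lyticase-Msg they were 7 with a floor under low values and 0 with an estimated correlation or fry, and 3 to 6 with single arrays left out. SDS-Msg reached 1 list with genes above the median level (type I interferon), with the floor and with the trend and robust model (cholesterol synthesis for both), and 0 to 1 with single arrays left out. Between the preparations the 4 lists became 1 with median centring, with a further quantile normalization and with array weights, 2 without media replicate 3 and lyticase-Msg replicate 2, 0 with an estimated correlation or fry, and 2 to 4 with single arrays left out. Without lyticase-Msg replicate 3 the number stayed at 4, but only NF-kB was among the earlier lists. The same-numbered arrays do not pair: the 18 correlations of their deviations ran from -0.21 to 0.16, and 4 of 12 arrays correlated best with their own number. With the replicate block LPS gave 7403 genes, the lists stayed at 15, 4 and 0 against media, and between the preparations 3 remained (cytokines at adjusted p = 0.0677). The correlation of LPS and lyticase-Msg responses was 0.172 over genes above the median level, 0.0797 with no array in common and 0.182 to 0.245 with single arrays left out. For LPS and SDS-Msg these were 0.0749, 0.0120 and 0.116 to 0.196, and lyticase-Msg with SDS-Msg ran from 0.490 to 0.692. Of the called genes named in the text 0 changed sign, while Klrb1c went to 0 with the floor. The other called genes were not followed one by one. Uncalled differences did: Ifit1 with lyticase-Msg went from -0.11 to 0.021 without lyticase-Msg replicate 2, and Cxcl10 with SDS-Msg from 0.14 to -0.058 without SDS-Msg replicate 1. Detection limits are unknown without scanner files, so the size of a change from below background is uncertain, and saturation near the highest values (14.2) was not tested.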

Other observations

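LPS also moved single genes of 4 lists that camera did not call in the main fit. Fry called 3 of them: lysosome and phagocytosis (adjusted p = 0.000449), NRF2 (0.00141) and glycolysis (2.91e-07), and not the unfolded protein response (0.0511). Camera called glycolysis with genes above the median level (adjusted p = 0.03655) and after cyclic loess (0.01425), and NRF2 after cyclic loess (0.0497). Of 22 lysosome and phagocytosis genes 6 rose and 10 fell by either count (median -0.10, camera, adjusted p = 0.442): the scavenger receptor Marco rose 3.67-fold and Atp6v0d2, a subunit of the proton pump that acidifies lysosomes, was 3.30-fold lower. Among 17 genes of the unfolded protein response and amino acid stress 4 rose and 4 fell by either count (median -0.078, adjusted p = 0.792), with Atf3 up 1.66-fold and Sesn2 2.10-fold lower. Of 14 NRF2 and oxidative stress genes 5 rose and 3 fell, and 6 and 3 adjusted over the list alone (median 0.10, adjusted p = 0.179), with the metallothionein Mt2 up 1.76-fold and Gclc, the enzyme that starts glutathione synthesis, 1.56-fold lower. Glycolysis genes gave a median of -0.030 but a mean of 0.21 and a test direction up (adjusted p = 0.0871). By either count 6 of 16 rose and 0 fell, with the regulator Pfkfb3 up 2.45-fold from a level of 9.65.

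The comparison of Mterf2 across groups and the slopes and correlations below were chosen after the results were seen. Mterf2, named for a mitochondrial transcription factor, was chosen after its values were seen as the gene with the largest Msg difference among those LPS changed 2-fold. Its log2 signal was 5.81 ± 0.24 in media, 4.76 ± 0.10 with LPS (difference -1.04, adjusted p = 0.000121), 4.76 ± 0.13 with lyticase-Msg (-1.05, adjusted p = 0.261) and 4.80 ± 0.30 with SDS-Msg (-1.01, adjusted p = 0.248). All 9 treated arrays lie at or below 5.14 and the lowest media array at 5.53. Every group mean lies under the 25th percentile of the arrays (5.94 to 6.02), so the size of this difference is uncertain. The contrasts share the media arrays, so a fall common to the 3 treatments and a shift of the media arrays were not told apart.

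With no array in common, slopes were fitted over genes chosen by a 2-fold difference of the LPS contrast alone. Lyticase-Msg minus media had a slope of 1.28% (jackknife SE 0.65) on LPS minus SDS-Msg over 975 genes, with 1.28% as the highest other of 10 splits. SDS-Msg minus media had -0.088% (SE 0.67) on LPS minus lyticase-Msg over 926 genes, with 1.22% as the highest other. Lyticase-Msg minus SDS-Msg had 1.38% (SE 0.64) on LPS minus media over 988 genes, with 1.42% as the highest other. Over the 986 genes called 2-fold between LPS and media the slopes were 1.66%, 0.338% and 1.32%, the highest others being 1.34%, 0.97% and 1.39%, but there the media arrays also chose the genes of the first 2. Across all 19938 genes lyticase-Msg minus SDS-Msg correlated with LPS minus media at r = 0.0774. Over the same genes lyticase-Msg minus media correlated with LPS minus SDS-Msg at 0.0796, and SDS-Msg minus media with LPS minus lyticase-Msg at 0.0120.

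The 3 Msg contrasts had 1550, 966 and 890 genes at an unadjusted p under 0.05 for lyticase-Msg against media, SDS-Msg against media and lyticase-Msg against SDS-Msg, where 997 are given by chance on average. Genes are not independent and the spread of such counts was not estimated, so an excess over 997 is not a test. No samples with lyticase or SDS alone were used here, so effects of a purification reagent were not tested.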
